A study of Homo sapiens with 48 samples.

How the data were processed

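RNA from HaCaT keratinocytes was measured on 48 Illumina HumanHT-12 v4 BeadArrays, 12 on each of 4 BeadChips. Per the labels, cells were plated in medium with 10% serum for 24 h, kept without serum for 24 h, and then given medium with 1% serum and EBC-46, EBC-211 or vehicle for 24 h or 48 h. RNA was isolated with RNeasy columns, amplified to biotinylated cRNA with a TotalPrep kit and stained with streptavidin-Cy3. Doses are written here in µg/ml as in the treatment protocol, though the labels of single samples have mg/ml. Per the submitters' processing notes, signals were exported with GenomeStudio, whose version the sources used here do not give. The deposited table before normalization holds an intensity for each of 47323 probes, the mean bead signal on a linear scale with no background subtracted, and beside each intensity a detection p-value. That deposited p-value ranks the signal against the negative control probes of the array, and its smallest step corresponds to 769 such probes. It is missing for 92 probes. The deposited processed table holds log2 values. The labels do not say how the authors made them, and log2 of the intensity after quantile normalization, centred on the median of each probe, matched them to within 0.00032. Their column medians lay between -0.00329 and 0.00194. Samples were grouped by compound, dose and time as the labels give them, 4 arrays in each of 12 groups. Replicates 1 to 4 of every group lay on BeadChips 1 to 4, and each group took the same section of every BeadChip, so section and group cannot be told apart.

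The non-normalized intensities were background corrected with detection p-values, offset by 16 and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table and version 2.0.0 of jsonlite for reading and writing. Probes with a detection p under 0.01 on at least 4 arrays were kept, 17709 in number. The platform's probe annotation lists 1 symbol for 30113 probes and several for 8, and 17202 were not listed. Of those with 1 symbol, 30074 matched a current gene by its Entrez number, and 0 symbols needed an update. For each symbol the probe with the highest mean was kept, and probes without a single symbol stayed as separate features, so 14458 features were tested, 10424 genes and 4034 unnamed probes. The median intensity per array was 99.3 to 145.1, the mean 343.41 to 530.13, and 27.1% to 33.4% of probes were detected. No 2 arrays were duplicates (highest correlation 0.99301). Principal component 1 held 32.9% of the variance, and component 2 held 16.6%. On component 2 the arrays of BeadChips 1 and 2 had positive scores and those of 3 and 4 negative ones, except replicate 4 of EBC-211 at 10 µg/ml and 48 h. limma fitted 1 coefficient for each group (36 residual degrees of freedom, prior 6.292) with empirical Bayes moderation and a mean-variance trend. P-values were adjusted by Benjamini and Hochberg over the 14458 features within each comparison, and a feature was called at an adjusted p under 0.05. Calls of at least 2-fold were also counted. In this fit, which leaves differences between BeadChips in the spread, 95% confidence intervals had a median half-width of 0.38 on the log2 scale. Simulated data took each gene's mean and spread from the real arrays, with independent normal noise and no BeadChip effect. Recovery on the real arrays may therefore differ. In the simulated data, tests of EBC-46 at 10 µg/ml against vehicle at 48 h recovered 35.4%, 83.6% and 100% of changes of 1.41, 2 and 4-fold, with 7 false among 155 calls. The comparison of the compounds at 10 µg/ml and 48 h recovered 20.0%, 84.3% and 100%, with 11 false among 140 calls. Where a gene was undetected on all 4 arrays of a group, its fold change is given as a bound, with the gene set at the lowest value of a detected probe on each of those arrays, or at its own value where higher. For a named gene detected on 1 of 4 arrays of a group a bound is given in the same way. A gene detected on 2 or 3 of 4 keeps its fitted value, which rests in part on signals near background. In a difference of effects a gene detected on fewer than 2 arrays of a group it rests on is not named.

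The comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. They were each treated group against vehicle of its time, the compounds against each other at matched dose and time, 10 against 0.1 µg/ml at 48 h for each compound, vehicle at 48 h against 24 h, and the difference between the effects of 10 µg/ml at 48 h and 24 h. Comparisons of 10 with 0.001 µg/ml, and of 48 h with 24 h in treated groups, were added after the data were seen. Genes named for a comparison with vehicle are the 8 largest increases and 8 largest decreases among called genes with a symbol, at least 2-fold, the same direction on all 4 BeadChips and detected on all arrays of at least 1 group. Of each list the 3 called members with the largest change were added. In other comparisons these numbers were 6 and 1, and any protein kinase C or D gene may be named. Names from outside the rule are said to have been chosen after the values were seen. The lists were tested with camera of limma with a preset correlation between genes of 0.01, two-sided, adjusted over the lists of a comparison. A test with a correlation estimated from the residuals is given beside it. Those residuals are of the fit on groups alone, so differences between BeadChips enter the estimate. They cover basal, differentiating, wound-activated and simple or mucosal keratin programmes, metalloproteinases, plasminogen activation, migration integrins, EGF receptor ligands, other growth factors, ERK feedback, AP-1, protein kinase C and D, NF-kB feedback, chemokines, interleukins and interferon response. The others are DNA replication, mitosis, cell cycle inhibitors with p53 targets, junctions, epithelial-mesenchymal transition, TGF-beta targets, unfolded protein stress, heat shock, NRF2 targets, cholesterol synthesis, lipid synthesis, glycolysis with hypoxia, the respiratory chain, ribosomal proteins, prostaglandins, hyaluronan, and markers of immune cells, fibroblasts, melanocytes and endothelial cells. Lists with fewer than 3 measured members, the last 3 named, were not tested. Of the wound-activated keratinocyte list, the keratin genes KRT6A, KRT6B and KRT17 were not measured. Fold changes of the compounds against the same vehicle arrays were compared by Pearson correlation and covariance over 14458 features, with values from 100 simulated pairs of unchanged groups, and with vehicle arrays split 2 and 2 in all 6 ways. The genes called with both were counted with independent lists, the simulated groups and the split arrays beside them, the last 2 added after the data were seen.

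The labels give each array's BeadChip, and replicates of the same number share it. Deviations of arrays from their group means correlated between arrays of the same number with a mean r of 0.374 (260 of 264 pairs over 0.1, lowest 0.0695). Between replicates 1 or 2 and 3 or 4 the mean was -0.346 over 576 pairs, and 47 of 48 arrays correlated best with their own number. The BeadChip therefore served as a block in a further fit, given beside counts of calls. Alternatives written beforehand were quantile normalization without background correction, median centring in place of quantile normalization, the deposited processed values, no filter, detection on all 48 arrays, the block, array weights, every probe tested, robust moderation, the compared groups alone, and each replicate number left out in turn. Fits on replicates 1 and 2 or on 3 and 4, and without single arrays that stood apart, were added after the data were seen. Each count was also set against the 35 ways of splitting the 8 arrays 4 and 4, or against 99 random groupings for the differences of effects, and 99 drawn within replicate numbers, as they are and after the additive effects of compound, time and BeadChip were taken out, added after the data were seen. Of the 35, 8 part the arrays of each replicate number as the real grouping does. Array measures, and the values of each gene named in the text within its groups, were checked for a single array apart from the other 3 by Dixon's ratio of gap to range, which picks out about 1 in 20 groups by chance. The 92 probes without a detection p were left out of the tests. Genome positions were not analysed here.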

Results

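HaCaT cells, a spontaneously immortalised line of human keratinocytes, were profiled on Illumina HumanHT-12 v4 BeadArrays, on which each probe gives a fluorescence signal for a transcript. The 48 arrays form 12 groups of 4. Cells received vehicle for 24 h or 48 h, or EBC-46 or EBC-211 at 0.001 or 10 µg/ml for 24 h or 48 h, or either compound at 0.1 µg/ml for 48 h alone. EBC-46 is tigilanol tiglate, an epoxy-tigliane that activates protein kinase C, and EBC-211 is known here by its code only. The treatment protocol gives the doses in µg/ml, whereas the labels of single samples give the same figures in mg/ml. The sources used here do not settle which is meant. The series title sets the compounds in keratinocyte wound healing, so the comparisons ask which transcripts differ from vehicle at each dose and time, whether the compounds differ from each other, and how the cultures change between 24 h and 48 h. The median signal per array lay between 99.3 and 145.1 (median of the arrays 119.65), and between 27.1% and 33.4% of probes were detected. Arrays of the same group correlated with r between 0.955 and 0.992. With 4 arrays per group, the number of arrays limits the precision. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. Log2 changes are given with their standard errors, n = 4 arrays in each group, from limma, and a gene is said to have changed where its adjusted p was under 0.05. Where a gene was detected on no more than 1 of the 4 arrays of a group, a bound on its fold change is given.

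At 24 h, interferon response and chemokine transcripts were lower with EBC-46 at 10 µg/ml than in vehicle of the same time. Each group took the same section of every BeadChip, so placement cannot be told from a response to a compound, here and below. IFNB1, which encodes interferon beta, changed by -3.45 ± 0.25 on the log2 scale (SE, n = 4), and the interferon-induced chemokine gene CXCL10 by -2.96 ± 0.30. S100A7 and S100A8, which encode antimicrobial alarmins, changed by -4.58 ± 0.67 and -4.14 ± 0.67, and CFB, a gene of the alternative complement pathway, by -3.09 ± 0.43. TNF was undetected on the treated arrays and at least 5.00-fold lower. Among the increases were the long noncoding RNA MANCR (2.99 ± 0.19), FST, which encodes the activin antagonist follistatin (1.98 ± 0.23), the chloride channel gene ANO1 (2.07 ± 0.15), and ETV4, an ETS transcription factor gene induced by ERK signalling (1.86 ± 0.22). At 0.001 µg/ml the changes included IFNB1 (-3.02 ± 0.25), the antiviral effector gene RSAD2 (-2.38 ± 0.20), the collagenase gene MMP1 (2.14 ± 0.26) and MANCR (2.51 ± 0.19). In all, 3174 of the 14458 genes and unnamed probes tested changed at 10 µg/ml, 1598 up and 1576 down, of which 568 changed at least 2-fold. At 0.001 µg/ml 2998 changed, 1495 up and 1503 down, with 432 at least 2-fold. With the BeadChip as a block the counts were 4665 and 4500. Of the changed genes, 97.1% and 97.8% had the same direction on all 4 BeadChips. The genes were called on these same BeadChips, so such shares, here and below, are no separate test. Without replicate 3 or without replicate 4 of every group, the count for 0.001 µg/ml was 1986 or 1969.

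With EBC-211 at 24 h, IFNB1 was lower and MANCR higher than in vehicle of the same time at both doses. At 10 µg/ml, S100A7 changed by -3.97 ± 0.67, IFNB1 by -3.29 ± 0.25, and CD74, the invariant chain gene of class II antigen presentation, by -2.78 ± 0.42. GBP2, an interferon-induced guanylate-binding protein gene, was detected on 1 of the 4 treated arrays and at least 5.94-fold lower. EGR1, an immediate early gene, changed by -2.01 ± 0.12. Increases included MANCR (2.89 ± 0.19), FST (2.18 ± 0.23), the DNA replication licensing gene CDT1 (1.92 ± 0.50) and ETV4 (1.90 ± 0.22). At 0.001 µg/ml increases included the metalloproteinase genes MMP1 (2.50 ± 0.26) and MMP10 (1.93 ± 0.27), with MANCR at 2.24 ± 0.19. IFNB1 changed by -2.56 ± 0.25 and IFNL1, a type III interferon gene, by -2.25 ± 0.29. With 10 µg/ml 3521 genes changed, 1707 up and 1814 down, 590 of them at least 2-fold, and with 0.001 µg/ml 2410 changed, 1234 up and 1176 down, 292 at least 2-fold. A fit with the BeadChip as a block called 5056 and 3919, and 95.97% and 98.6% of the changed genes had the same direction on all 4 BeadChips. Without replicate 3 or without replicate 4 of every group, the count for 10 µg/ml was 2268 or 2347, and that for 0.001 µg/ml 1456 or 1539.

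The gene lists fixed before the data were examined showed which groups of genes differed from vehicle at 24 h. Counts of 4 are given in the order EBC-46 at 0.001 and 10 µg/ml and EBC-211 at 0.001 and 10 µg/ml, and camera set each list against all other genes with a preset correlation. Of the 35 measured genes of the interferon response, 24, 30, 23 and 28 fell and none rose, or 29, 32, 28 and 30 adjusted over the list alone, with a median change at EBC-46 10 µg/ml of -1.48. Its call held with an estimated correlation in all 4. IFI27, an interferon-stimulated gene, changed by -2.64 and -2.77 at 10 µg/ml of EBC-46 and EBC-211. Of the 13 chemokine genes 8, 9, 5 and 9 fell (8, 9, 7 and 9 adjusted over the list alone). An estimated correlation gave this list adjusted p values of 0.159, 0.32 and 0.0864 for EBC-46 at 0.001 µg/ml, EBC-211 at 0.001 µg/ml and EBC-211 at 10 µg/ml. Of the 18 interleukin and cytokine genes 5, 8, 4 and 6 fell (5, 9, 4 and 9 adjusted over the list alone). The adjusted p values of the list were 0.153, 0.0595, 0.267 and 0.0864 with an estimated correlation. Of the 16 feedback targets of NF-kB 8, 12, 6 and 12 fell (12, 12, 9 and 13 adjusted over the list alone), among them RELB, an NF-kB subunit gene, at -2.22 with EBC-46 and -1.85 with EBC-211 at 10 µg/ml. Under an estimated correlation the adjusted p values of the list for EBC-46 at 0.001 µg/ml, EBC-211 at 0.001 µg/ml and EBC-211 at 10 µg/ml were 0.106, 0.213 and 0.0573. The AP-1 and immediate early list, with 21 members, had 8, 10, 6 and 9 down and 1, 3, 1 and 3 up (13, 10, 8 and 9 down adjusted over the list alone). ATF3, a stress-induced transcription factor gene, changed by -1.59 and -1.76 at 10 µg/ml. Among 18 targets of TGF-beta and SMADs 6, 9, 5 and 6 fell (9, 9, 7 and 6 adjusted over the list alone). The AP-1 and TGF-beta calls held with an estimated correlation in all 4. At most 1 chemokine, NF-kB or TGF-beta list member rose in any of the 4.

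Cell cycle genes were higher than in vehicle at 24 h. In the same order of 4, 34, 35, 34 and 36 of 39 DNA replication and G1/S genes rose (35, 36, 34 and 37 adjusted over the list alone), with medians of 0.91, or 0.90 with undetected members at their bound, 0.94, or 0.92 with undetected members at their bound, 0.97, or 0.94 with undetected members at their bound and 1.04, and the call held with an estimated correlation in all 4. POLE2, a DNA polymerase epsilon subunit gene, changed by 1.61 and 1.55 at 10 µg/ml. Of 39 mitosis and G2/M genes 23, 25, 24 and 30 rose (31, 33, 32 and 34 adjusted over the list alone). The calls had adjusted p values of 0.153, 0.115, 0.149 and 0.0864 with an estimated correlation. Of 19 cell cycle inhibitors and p53 targets 10, 11, 10 and 10 fell (10, 11, 10 and 11 adjusted over the list alone), which held with an estimated correlation in all 4, and CDKN1A, the gene of the cell cycle inhibitor p21, changed by -1.79 and -1.54 at 10 µg/ml. In the ERK pathway feedback list, with 17 members, 7, 7, 4 and 7 rose and 2, 2, 2 and 2 fell (7, 8, 4 and 10 up adjusted over the list alone). The list was called up at both 10 µg/ml doses with either correlation. It was called for EBC-46 at 0.001 µg/ml with the preset correlation alone (adjusted p = 0.0537 with an estimated correlation), and for EBC-211 at 0.001 µg/ml its adjusted p was 0.177. Of 11 protein kinase C and D genes 2, 0, 1 and 2 fell and none rose (2, 0, 0 and 2 down adjusted over the list alone). PRKCD, which encodes protein kinase C delta, changed by -0.67 with EBC-46 at 0.001 µg/ml and -0.67 with EBC-211 at 10 µg/ml. The list was called in none of the 4.

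Of the lists of keratinocyte state at 24 h, again in that order of 4, 12 genes of wound-activated keratinocytes, such as S100A7 and S100A8, had 6, 5, 1 and 5 down (6, 5, 3 and 5 adjusted over the list alone) and 0, 0, 1 and 0 up, called down in 3. With an estimated correlation the adjusted p values for EBC-46 at 0.001 µg/ml, EBC-46 at 10 µg/ml and EBC-211 at 10 µg/ml were 0.573, 0.262 and 0.33. Basal keratinocyte genes, 11 in number, had 5, 5, 3 and 5 down (5, 6, 3 and 5 adjusted over the list alone), called in 3, with KRT15, a basal keratin gene, at -1.68 and -1.66 at 10 µg/ml. An estimated correlation gave this list adjusted p values of 0.153, 0.0595 and 0.0864 for EBC-46 at 0.001 µg/ml, EBC-46 at 10 µg/ml and EBC-211 at 10 µg/ml. Of 23 genes of desmosomes and cell junctions 11, 11, 7 and 10 fell (11, 12, 9 and 11 adjusted over the list alone), and CDH1, the E-cadherin gene, changed by -1.16 and -0.89 at 10 µg/ml. The adjusted p values of the list were 0.164, 0.134, 0.32 and 0.345 with an estimated correlation. The matrix metalloproteinase list, with 13 members, was called up at 0.001 µg/ml of both compounds, where 5 and 6 rose (5 and 6 adjusted over the list alone). Under an estimated correlation the adjusted p values of the list for EBC-46 at 0.001 µg/ml and EBC-211 at 0.001 µg/ml were 0.169 and 0.149. Of 16 other settings of the analysis, the estimated correlation and fits on fewer arrays among them, 11 lost the call for EBC-46 (adjusted p up to 0.23) and 3 that for EBC-211. The list of migration integrins and provisional matrix, with 16 members, was called down at the same dose, where 8 and 3 fell (9 and 6 adjusted over the list alone). The calls for EBC-46 at 0.001 µg/ml and EBC-211 at 0.001 µg/ml had adjusted p values of 0.159 and 0.213 with an estimated correlation. Of 6 immune cell markers, CD74 and HLA-DRA among them, 3, 3, 3 and 3 fell (3, 3, 3 and 4 adjusted over the list alone). With an estimated correlation the adjusted p values were 0.153, 0.0651, 0.213 and 0.0864. Keratinocytes too express CD74 and HLA-DRA, both of class II antigen presentation, when exposed to interferon gamma. Terminal differentiation, with 20 members, was called down with EBC-46 at 10 µg/ml, where 7 fell (8 adjusted over the list alone) and 2 rose. An estimated correlation gave this list an adjusted p of 0.308 for EBC-46 at 10 µg/ml. Unfolded protein and amino acid stress, with 23 members, was called up at 10 µg/ml of both compounds, where 8 and 8 rose and 3 and 3 fell (8 and 8 up adjusted over the list alone). The adjusted p values of the list were 0.38 and 0.378 with an estimated correlation for EBC-46 at 10 µg/ml and EBC-211 at 10 µg/ml. Heat shock genes, 16 in number, were called up with EBC-211 at 10 µg/ml with either correlation, where 9 rose (9 adjusted over the list alone), HSPH1, a chaperone gene, by 0.89. In these comparisons at most 1 basal and 1 junction gene rose, and 1 metalloproteinase gene fell. The remaining 14 lists, protein kinase C and D included, were called in none of the 4. Besides the metalloproteinases, calls at 24 h lost in at least 4 of the 16 settings were migration integrins at 0.001 µg/ml of EBC-46 and EBC-211 (5 and 5 settings, adjusted p up to 0.164 and 0.269), immune cell markers for EBC-211 at 0.001 µg/ml (5, up to 0.331), terminal differentiation for EBC-46 at 10 µg/ml (5, up to 0.308), wound-activated keratinocytes for EBC-46 at 0.001 µg/ml (4, up to 0.573), unfolded protein stress for EBC-46 at 10 µg/ml (4, up to 0.38) and junctions for EBC-211 at 10 µg/ml (4, up to 0.345).

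At 48 h, the increases with EBC-46 at 10 µg/ml against vehicle of the same time included KRT13, KRT15, SOX2 and MMP1, and the decreases SAA1, S100A7 and IL6. KRT13, a keratin gene of mucosal epithelia, changed by 2.84 ± 0.26 on the log2 scale (SE, n = 4), KRT15 by 2.71 ± 0.25, the transcription factor gene SOX2 by 2.76 ± 0.17 and MMP1 by 2.67 ± 0.26. SAA1, which encodes the acute phase protein serum amyloid A, changed by -4.73 ± 0.62, S100A7 by -4.49 ± 0.67 and the cytokine gene IL6 by -4.15 ± 0.27. On the treated arrays IL32, a cytokine gene, was undetected and at least 20.7-fold lower. UBD, a ubiquitin-like modifier gene induced by interferon, and the chemokine gene CCL20 were undetected too and at least 18.6-fold lower and at least 11.6-fold lower. At 0.001 µg/ml, KRT13 changed by 3.08 ± 0.26, KRT15 by 2.58 ± 0.25 and IL32 by -3.29 ± 0.47, and at 0.1 µg/ml these values were 2.57 ± 0.26, 2.41 ± 0.25 and -4.08 ± 0.47. UBD was detected on 1 of the 4 treated arrays at each of these doses, and at least 18.2-fold lower and at least 17.8-fold lower. In rising order of dose, 3224, 3183 and 3480 genes changed, 1736, 1784 and 1892 of them up, and 656, 719 and 832 changed at least 2-fold. With the BeadChip as a block the counts were 4807, 4627 and 4972. The same direction on all 4 BeadChips was seen for 90.97%, 97.1% and 96.3% of the changed genes. 1 array of the 0.001 µg/ml group, replicate 2, stood apart from the other 3, and without it 2883 genes changed at that dose. Fitted on the arrays of the compared groups alone, the count at that dose was 1433.

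With EBC-211 at 48 h, KRT13 and KRT15 were higher and IL32 and UBD lower than in vehicle at all 3 doses. At 10 µg/ml MMP1 changed by 2.95 ± 0.26, the cytidine deaminase gene APOBEC3B by 2.79 ± 0.21, SOX2 by 2.75 ± 0.17, KRT15 by 2.69 ± 0.25 and KRT13 by 2.38 ± 0.26. IL32 changed by -4.31 ± 0.47, CXCL10 by -3.77 ± 0.30 and IL6 by -3.66 ± 0.27. UBD and CCL20 were each detected on 1 of the 4 treated arrays, at least 18.4-fold lower and at least 11.2-fold lower. At 0.001 µg/ml KRT13 changed by 2.97 ± 0.26, KRT15 by 2.65 ± 0.25 and IL32 by -2.89 ± 0.47, and UBD was detected on 1 of the 4 treated arrays and at least 16.7-fold lower. At 0.1 µg/ml KRT13 changed by 2.66 ± 0.26, KRT15 by 2.12 ± 0.25 and IL32 by -4.10 ± 0.47, and UBD was undetected on the treated arrays and at least 18.1-fold lower. In rising order of dose, 2652, 3282 and 3356 genes changed, 1456, 1779 and 1772 of them up, and 601, 766 and 722 changed at least 2-fold. Counts with the BeadChip as a block were 4124, 4772 and 4987. The same direction on all 4 BeadChips was seen for 97.96%, 97.3% and 95.7% of the changed genes. Without replicate 4 of every group the count at 10 µg/ml was 2232, and at 0.001 µg/ml it was 1730.

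**Figure D1:**
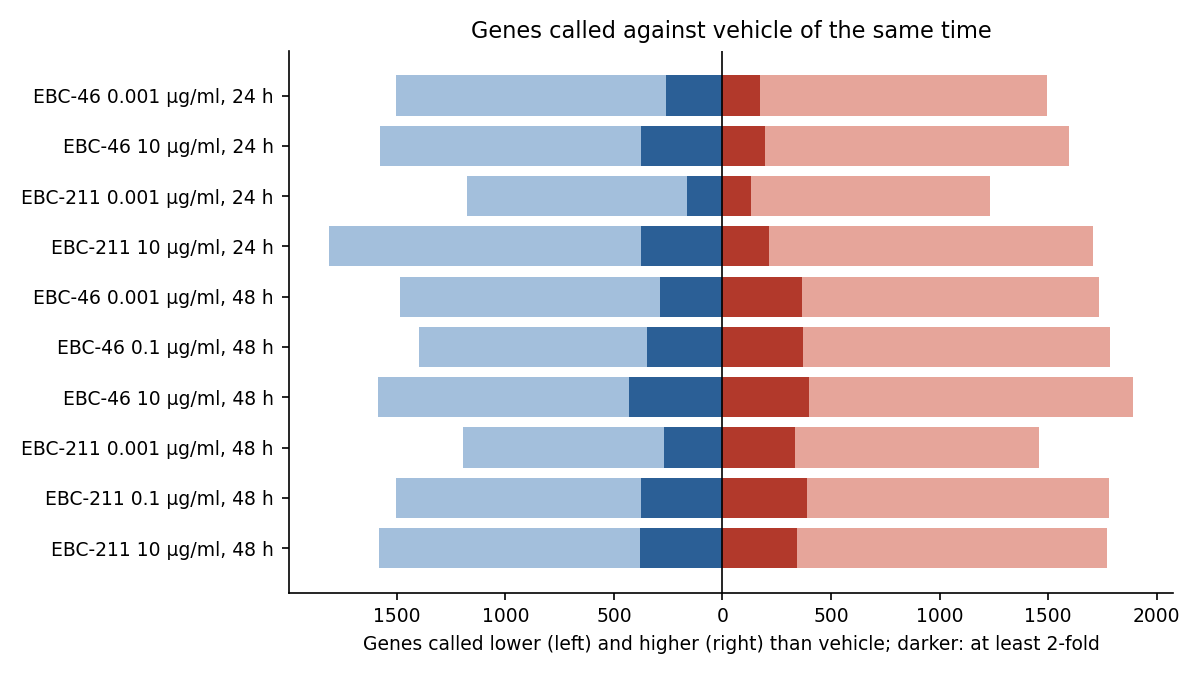
Genes and unnamed probes that passed limma (adjusted p under 0.05) against vehicle of the same time, by compound, dose and time. Bars to the right count increases and bars to the left decreases, with the darker part of each bar for changes of at least 2-fold. The longest bars to the right are the 1892 increases with EBC-46 at 10 µg/ml and 48 h, and the shortest are the 1234 with EBC-211 at 0.001 µg/ml and 24 h.

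Mitotic genes were higher than in vehicle of the same time at 48 h, and here a gene rose or fell against that vehicle. Counts of 6 are given in the order EBC-46 at 0.001, 0.1 and 10 µg/ml and then EBC-211 at the same doses. Of 39 mitosis and G2/M genes 39, 38, 39, 38, 37 and 38 rose (39, 38, 39, 38, 39 and 38 adjusted over the list alone), with medians from 1.70 to 1.83. CENPA, the gene of the centromeric histone, changed by 2.33 and 2.24 at 10 µg/ml, and KIF20A, a kinesin gene of cytokinesis, by 2.23 and 2.10. Of 39 DNA replication and G1/S genes 32, 29, 29, 31, 30 and 28 rose and 2, 2, 1, 1, 3 and 2 fell (33, 32, 32, 33, 33 and 28 up adjusted over the list alone), with PRIM1, a primase subunit gene, at 2.39 and 2.14 at 10 µg/ml. Of 19 cell cycle inhibitors and p53 targets 7, 7, 6, 7, 9 and 8 fell and 2, 2, 3, 1, 1 and 2 rose (7, 8, 8, 8, 10 and 8 down adjusted over the list alone). These calls held with an estimated correlation in all 6.

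Inflammatory and wound-associated genes were lower than in vehicle at 48 h. Of 35 interferon response genes 27, 25, 27, 25, 28 and 25 fell and none rose (27, 28, 29, 25, 29 and 26 down adjusted over the list alone), with IFI27 at -3.98 and -3.72 at 10 µg/ml. Of 13 chemokine genes 9, 9, 10, 9, 9 and 9 fell (9, 9, 10, 9, 10 and 10 adjusted over the list alone) and 2, 1, 2, 2, 2 and 2 rose. Of 18 interleukin and cytokine genes 11, 10, 12, 10, 10 and 10 fell (11, 11, 12, 10, 10 and 11 adjusted over the list alone). Of 16 NF-kB feedback targets 12, 13, 14, 10, 13 and 13 fell (14, 13, 15, 12, 13 and 15 adjusted over the list alone), with SOD2, the mitochondrial superoxide dismutase gene, at -3.01 and -2.41 at 10 µg/ml. Under an estimated correlation the adjusted p value of the list for EBC-211 at 0.001 µg/ml was 0.0518. Of 21 AP-1 and immediate early genes 6, 6, 8, 5, 5 and 8 fell (6, 7, 8, 8, 5 and 9 adjusted over the list alone), with JUN, an AP-1 subunit gene, at -2.57 and -2.77. The interferon, chemokine, interleukin and AP-1 calls held with an estimated correlation in all 6. In each of the 6 the interleukin call was lost in 1 of the 16 other settings (adjusted p up to 0.427, camera). Of 12 wound-activated keratinocyte genes 7, 10, 11, 2, 9 and 11 fell and none rose (9, 11, 11, 4, 10 and 12 down adjusted over the list alone), with a median at EBC-46 10 µg/ml of -3.24, or -2.91 with undetected members at their bound and PI3, the elafin gene, at -4.08. On the array of EBC-46 at 0.001 µg/ml that stood apart, 11 of these 12 genes lay below the value that group and BeadChip give. The calls for EBC-46 at 0.001 µg/ml, EBC-46 at 0.1 µg/ml, EBC-211 at 0.001 µg/ml, EBC-211 at 0.1 µg/ml and EBC-211 at 10 µg/ml had adjusted p values of 0.222, 0.0839, 0.384, 0.136 and 0.0507 with an estimated correlation. Of 18 TGF-beta and SMAD targets 4, 5, 7, 6, 6 and 6 fell (4, 6, 8, 6, 6 and 7 adjusted over the list alone). With an estimated correlation the adjusted p values for EBC-46 at 0.001 µg/ml and EBC-211 at 0.001 µg/ml were 0.0681 and 0.0691. Of 7 plasminogen activation genes 4, 4, 5, 4, 4 and 5 fell (4, 5, 5, 4, 4 and 5 adjusted over the list alone), with PLAUR, the urokinase receptor gene, at -2.28 and -2.12. An estimated correlation gave this list adjusted p values of 0.142, 0.0683 and 0.0507 for EBC-46 at 0.001 µg/ml, EBC-46 at 0.1 µg/ml and EBC-211 at 10 µg/ml. The call for EBC-46 at 0.001 µg/ml was lost in 8 of the 16 other settings (adjusted p up to 0.338). Of 16 migration integrin and provisional matrix genes 5, 6, 7, 6, 6 and 6 fell (5, 7, 7, 7, 6 and 6 adjusted over the list alone), with the integrin gene ITGA5, detected on 1 of 4 arrays at 10 µg/ml of each compound, at least 3.62-fold lower and at least 3.58-fold lower. The list was called in all 6 but EBC-46 at 0.001 µg/ml. The adjusted p values of the list were 0.0613 and 0.0507 with an estimated correlation for EBC-211 at 0.1 µg/ml and EBC-211 at 10 µg/ml. At most 1 member of the interleukin, AP-1, TGF-beta, plasminogen and integrin lists rose in any of the 6.

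Metabolic lists differed from vehicle too at 48 h. Of 19 cholesterol synthesis genes 11, 5, 5, 6, 9 and 2 rose (12, 5, 6, 9, 10 and 2 adjusted over the list alone), with TMEM97, a sterol-regulated gene, at 1.80 and 1.67 at 10 µg/ml. The list was called in all 6 but EBC-211 at 10 µg/ml, and each call held with an estimated correlation. Of 14 fatty acid and lipid synthesis genes 9, 9, 8, 9, 9 and 6 rose and 2, 3, 2, 1, 2 and 3 fell (9, 9, 9, 9, 9 and 8 up adjusted over the list alone), called in all but EBC-211 at 10 µg/ml. Under an estimated correlation the adjusted p value of the list for EBC-46 at 0.001 µg/ml was 0.0564. Of 28 respiratory chain genes 7, 10, 5, 8, 9 and 5 rose (10, 14, 5, 11, 11 and 5 adjusted over the list alone). The calls for EBC-46 at 0.001 µg/ml and EBC-211 at 10 µg/ml had adjusted p values of 0.0887 and 0.0507 with an estimated correlation. Of 26 glycolysis and hypoxia genes 7, 9, 12, 8, 9 and 10 fell (8, 11, 12, 8, 9 and 11 adjusted over the list alone), called in all but EBC-46 at 0.001 µg/ml. With an estimated correlation the adjusted p values for EBC-46 at 0.1 µg/ml, EBC-46 at 10 µg/ml, EBC-211 at 0.001 µg/ml, EBC-211 at 0.1 µg/ml and EBC-211 at 10 µg/ml were 0.107, 0.0527, 0.248, 0.22 and 0.0507. Of 16 heat shock genes 4, 6, 6, 3, 8 and 8 fell (6, 6, 6, 4, 8 and 8 adjusted over the list alone), called for EBC-46 at 0.1 µg/ml and for EBC-211 at all 3 doses. An estimated correlation gave this list adjusted p values of 0.0691 and 0.0522 for EBC-211 at 0.001 µg/ml and EBC-211 at 10 µg/ml. Of 33 ribosomal protein genes 7, 5, 8, 7, 7 and 9 rose (7, 4, 9, 7, 7 and 9 adjusted over the list alone), called for EBC-211 at 0.001 and 10 µg/ml. The adjusted p values of the list were 0.0893 and 0.0508 with an estimated correlation for EBC-211 at 0.001 µg/ml and EBC-211 at 10 µg/ml. Of 23 unfolded protein and amino acid stress genes 10, 12, 12, 10, 12 and 12 fell and 7, 6, 7, 7, 7 and 7 rose (11, 13, 13, 11, 13 and 12 down adjusted over the list alone), called down for EBC-46 at 0.1 and 10 µg/ml. Under an estimated correlation the adjusted p values of the list for EBC-46 at 0.1 µg/ml and EBC-46 at 10 µg/ml were 0.288 and 0.379. The ERK pathway feedback list was called up for EBC-46 at 0.1 µg/ml with 6 of 17 genes up (6 adjusted over the list alone). The call for EBC-46 at 0.1 µg/ml had an adjusted p of 0.0647 with an estimated correlation. It was lost in 9 of the 16 other settings (adjusted p up to 0.118). Immune cell markers were called down for EBC-46 at 10 µg/ml with 3 of 6 genes down (4 adjusted over the list alone). With an estimated correlation the adjusted p value for EBC-46 at 10 µg/ml was 0.155. Further calls at 48 h lost in at least 4 of those settings were the respiratory chain for EBC-46 at 0.001 µg/ml (7 settings, adjusted p up to 0.378), unfolded protein stress for EBC-46 at 10 µg/ml (6, up to 0.379), heat shock for EBC-211 at 0.001 and 10 µg/ml (6 and 4, up to 0.0691 and 0.0883), ribosomal proteins for EBC-211 at 0.001 µg/ml (5, up to 0.129) and immune cell markers for EBC-46 at 10 µg/ml (4, up to 0.155).

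Further lists were not called at 48 h, though single members changed. With EBC-46 at 10 µg/ml, 3 of 11 basal keratinocyte genes rose and 3 fell (3 and 3 adjusted over the list alone), 2 of 6 simple and mucosal keratin genes rose and 1 fell (2 and 2 adjusted over the list alone), and 2 of 20 terminal differentiation genes rose and 5 fell (3 and 6 adjusted over the list alone). In the same comparison, 4 of 13 metalloproteinase genes rose and 4 fell (4 and 4 adjusted over the list alone), 1 of 8 EGF receptor ligand and receptor genes rose and 3 fell (2 and 3 adjusted over the list alone), 2 of 12 other growth factor genes rose and 4 fell (2 and 4 adjusted over the list alone), and 2 of 11 protein kinase C and D genes rose and 0 fell (2 and 0 adjusted over the list alone). LRIG1, a negative regulator gene of EGF receptors, detected on 1 of 4 vehicle arrays, was at least 2.27-fold higher, and HBEGF, an EGF receptor ligand gene, changed by -1.74. Likewise, 2 of 23 desmosome and cell junction genes rose and 3 fell (2 and 4 adjusted over the list alone), 3 of 12 genes of epithelial-mesenchymal transition rose and 4 fell (3 and 4 adjusted over the list alone), and 5 of 22 NRF2 and oxidative stress genes rose and 5 fell (5 and 5 adjusted over the list alone). TAGLN, an actin-binding smooth muscle gene, was detected on 1 of 4 treated arrays and at least 4.77-fold lower. Last, 2 of 8 prostaglandin genes rose and 3 fell (2 and 3 adjusted over the list alone), and 2 of 10 hyaluronan and proteoglycan genes rose and 2 fell (2 and 2 adjusted over the list alone), HMMR, a hyaluronan receptor gene also active in mitosis, at 2.09. The marker lists of fibroblasts, melanocytes and endothelial cells had fewer than 3 measured members each and were not tested.

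**Figure D2:**
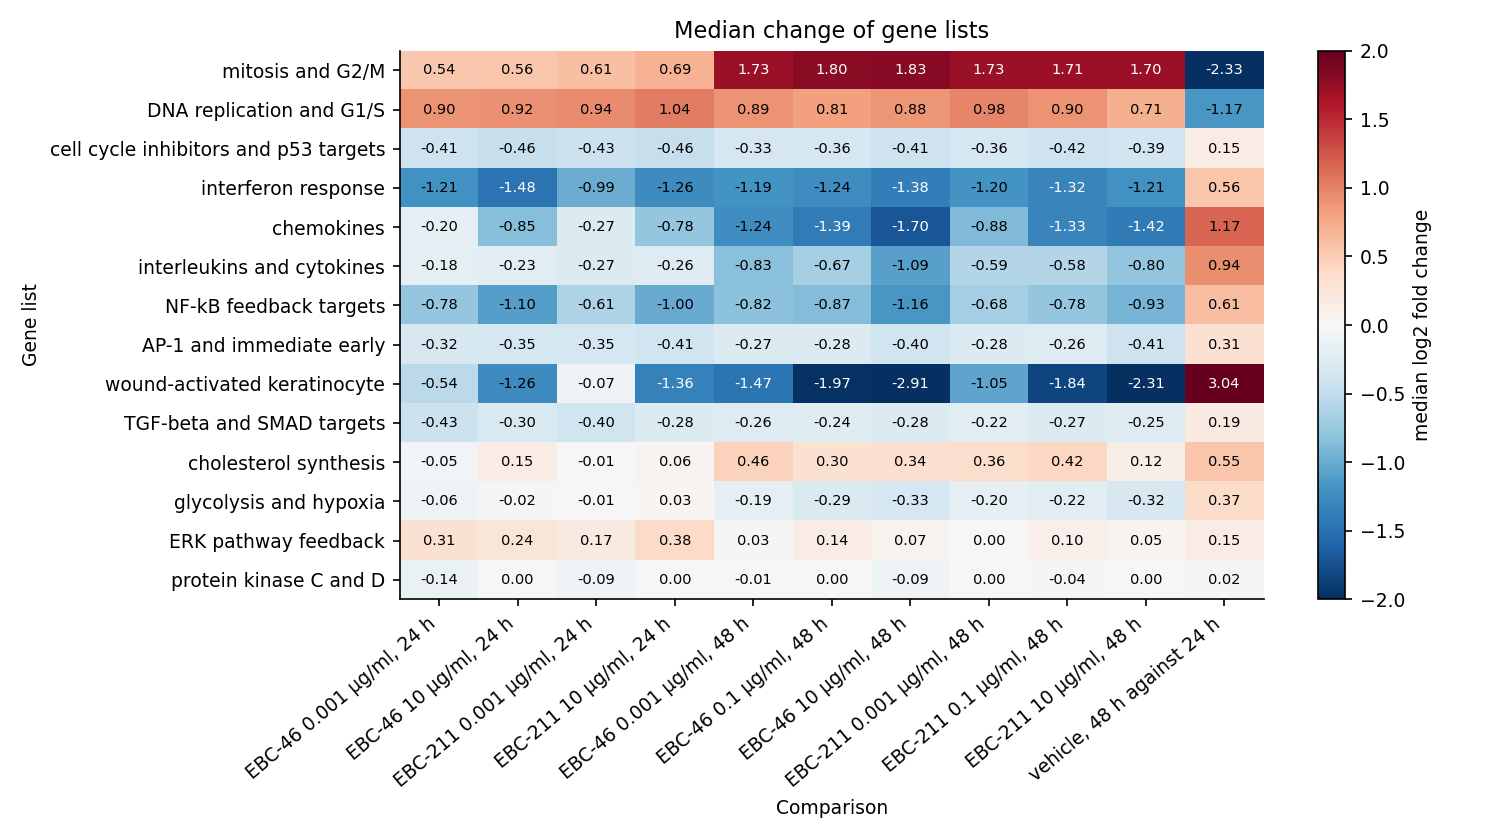
Median log2 fold change of 14 gene lists against vehicle of the same time, and in vehicle between 48 h and 24 h, with members undetected in a group set at their bound. Each row is a list and each column a comparison. Red is higher and blue lower, and the value is printed in each cell. The mitosis list stands at -2.33 in vehicle between 48 h and 24 h and at 1.83 with EBC-46 at 10 µg/ml and 48 h.

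The compounds were compared directly at matched dose and time to ask whether their responses differ. At 10 µg/ml and 24 h, 4 features differed. EGR1 was higher with EBC-46 than with EBC-211 by 0.85 ± 0.12 (adjusted p = 0.000175, limma), and KLF9, a Krüppel-like transcription factor gene induced by glucocorticoids, was detected on 1 of 4 arrays with EBC-46 and at least 1.97-fold lower (adjusted p = 0.00512). The rest, named after their values were seen, were ECM2, an extracellular matrix gene, at 0.73 ± 0.15, and the unnamed probe ILMN_1763775, undetected with EBC-46 and at least 1.27-fold lower than with EBC-211. All 4 had the same direction on all 4 BeadChips, though without replicate 1, 2, 3 or 4 of every group the count was 3, 2, 1 or 2, and on the arrays of the compared groups alone it was 0. In limma no feature differed at 0.001 µg/ml and 24 h, nor at 0.001, 0.1 or 10 µg/ml and 48 h, with 298, 1336, 339 and 489 features at an unadjusted p under 0.05, where 723 would be expected by chance. At 10 µg/ml and 24 h that number was 523. This fit leaves differences between BeadChips in the spread, so a count under 723 does not show that the compounds are alike. The 1336 features at 0.001 µg/ml and 48 h exceed 723. That comparison holds the EBC-46 array that stood apart, and the cause of the excess was not tested. The 95% confidence interval of a difference, from the same fit, had a median half-width of 0.38 on the log2 scale. Between 96.3% and 98.1% of features had an interval within a 2-fold difference either way, so smaller differences could not be excluded. With the BeadChip as a block, 1, 7, 4, 4 and 1 features differed, in the order 0.001 and 10 µg/ml at 24 h and 0.001, 0.1 and 10 µg/ml at 48 h. In the same order, 14, 4, 0, 7 and 12 of the 33 lists were called and 5, 1, 0, 3 and 0 held with an estimated correlation. Those that held at 0.001 µg/ml and 24 h were simple and mucosal keratins (median -0.29), basal keratinocyte genes (-0.15), terminal differentiation (-0.18, or -0.09 with undetected members at their bound) and NRF2 and oxidative stress (-0.05), all lower with EBC-46, and ERK pathway feedback (0.07), higher. At 10 µg/ml and 24 h it was heat shock (-0.07), and at 0.1 µg/ml and 48 h cholesterol synthesis (-0.14), AP-1 and immediate early genes (-0.08) and NRF2 and oxidative stress (0.06). No member of these lists passed over all genes, and adjusted over each list alone 1, 1, 0, 0, 0, 2, 0, 1 and 0 members passed in the order given.

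Fold changes against vehicle ran in parallel for the compounds. In the order 0.001 and 10 µg/ml at 24 h and 0.001, 0.1 and 10 µg/ml at 48 h, the correlation across genes, which are not independent replicates, was 0.925, 0.921, 0.888, 0.947 and 0.939. Both compounds were set against the same vehicle arrays, and simulated unchanged groups against those arrays gave mean correlations from 0.499 to 0.501. With the vehicle arrays split between the compounds, the mean correlation over the 6 splits was 0.714, 0.759, 0.718, 0.789 and 0.796. The lowest split gave 0.578, 0.653, 0.580, 0.690 and 0.682, and the highest 0.794, 0.821, 0.784, 0.847 and 0.850. A split leaves each compound fewer vehicle arrays, on other BeadChips than those of the other compound, which can lower the correlation too. The drop from the unsplit values therefore does not measure the noise of shared arrays alone. The covariance was 0.149, 0.198, 0.195, 0.234 and 0.256 against simulated values of 0.0215, 0.0214, 0.0215, 0.0215 and 0.0215. The differences, 0.127, 0.176, 0.173, 0.213 and 0.234, estimate the covariance left once the noise of shared arrays is taken out. An offset common to all vehicle arrays of a time would enter these differences, every split and the shared counts below. None of these values can therefore exclude such an offset. Of the genes that changed with both compounds, 2116, 2626, 2079, 2665 and 2757 in number, all had the same sign, with 1097, 1302, 1166, 1483 and 1500 up and 1019, 1324, 913, 1182 and 1257 down. Independent lists of those sizes, which leave out the shared vehicle arrays, would share 128, 189, 175, 219.5 and 232 increases and 122, 198, 123, 145 and 174 decreases. Simulated unchanged groups against those arrays, which leave out the effects, shared at most 1 called gene in 100 simulations. With the vehicle arrays split between the compounds, the lists shared on average 535, 710.0, 699, 865 and 863 increases and 505, 754, 522, 672 and 750.3 decreases, where independent lists would share 54.7, 89.2, 88.8, 114 and 119 and 50.4, 97.2, 59.9, 76.4 and 91.3, and at most 2 genes had opposite signs in any split.

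The step from 0.1 to 10 µg/ml at 48 h asks how far the response depends on dose. With EBC-46, 8 features differed between these doses. GLYATL2, a glycine acyltransferase gene, changed by -1.33 ± 0.21 from 0.1 to 10 µg/ml, KLF9 by -1.31 ± 0.19, TP53INP2, an autophagy gene, by -1.19 ± 0.21, and IDO1, which encodes the tryptophan-degrading enzyme induced by interferon, by -1.07 ± 0.22. The others, named after their values were seen, were the creatine kinase genes CKMT1A (-0.69) and CKMT1B (-0.71), the noncoding RNA UCA1 (-0.64) and the unnamed probe ILMN_1781104 (0.71). CKMT1A and CKMT1B are near-identical copies, so their probes may share signal. With EBC-211, 4 features differed. EGR1 changed by -0.59 ± 0.12, and named after their values were seen were ABCG1, a cholesterol export gene, at -0.89, and the unnamed probes ILMN_3202024 at 0.57 and ILMN_3275771 at 0.73. The counts with the BeadChip as a block were 34 and 70. Without replicate 1, 2, 3 or 4 of every group they were 4, 3, 1 or 1 for EBC-46 and 2, 0, 0 or 0 for EBC-211, and without replicate 4 of the EBC-211 10 µg/ml group alone, which lay on the side of BeadChips 1 and 2 on principal component 2, 1. On the arrays of the compared groups alone they were 17 and 1, and with median centring in place of quantile normalization 3 and 0. Of the 33 lists 10 were called for EBC-46 and 8 for EBC-211, and 5 and 3 held with an estimated correlation. These were lower at 10 µg/ml. For EBC-46 they were NF-kB feedback targets (median -0.32), interleukins and cytokines (-0.31, or -0.27 with undetected members at their bound), metalloproteinases (-0.18), NRF2 and oxidative stress (-0.09) and the respiratory chain (-0.06). For EBC-211 they were cholesterol synthesis (-0.28), AP-1 and immediate early genes (-0.14) and fatty acid and lipid synthesis (-0.21). Over all genes EGR1 alone of their members passed, and adjusted over each list alone 1, 3, 1, 0, 0, 6, 4 and 3 members passed in the order given.

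Between 24 h and 48 h, vehicle cultures gained transcripts of the wound-activated keratinocyte list and lost mitotic ones. KRT6A, KRT6B and KRT17, keratin genes of that list, were not measured, so its calls rest on the other members. The serpin genes SERPINB4 and SERPINB3 changed by 4.75 ± 0.52 and 4.15 ± 0.52 (SE, n = 4), SAA1 by 4.44 ± 0.62, PI3 by 4.11 ± 0.68, LCN2, the lipocalin gene, by 4.09 ± 0.57 and S100A7 by 3.75 ± 0.67. The kinesin genes KIFC1 and KIF20A changed by -2.89 ± 0.19 and -2.76 ± 0.20, and CENPA by -2.74 ± 0.16. In all 1661 genes changed, 743 up and 918 down, of which 494 changed at least 2-fold, and with the BeadChip as a block 2663 changed. 98.1% had the same direction on all 4 BeadChips, and without replicate 4 of every group the count was 1043. 38 of 39 mitosis genes (38 adjusted over the list alone) and 32 of 39 DNA replication genes (33 adjusted over the list alone) fell, with medians of -2.33 and -1.19, or -1.17 with undetected members at their bound. Of the respiratory chain genes 6 of 28 fell (7 adjusted over the list alone). All 12 wound-activated keratinocyte genes rose, over all genes and adjusted over the list alone, with a median of 3.04. Among chemokines 9 of 13, among interleukins 11 of 18, among NF-kB targets 7 of 16 and among interferon response genes 18 of 35 rose (10, 11, 8 and 25 adjusted over the list alone). Also called up were metalloproteinases, plasminogen activation, migration integrins, EGF receptor ligands, other growth factors, AP-1, TGF-beta targets, cholesterol synthesis, and glycolysis and hypoxia, with 4, 4, 5, 3, 3, 5, 4, 10 and 12 members up (10, 5, 5, 4, 4, 6, 7, 10 and 14 adjusted over the list alone). Each of these calls held with an estimated correlation. Unfolded protein stress and immune cell markers were called up with 7 and 2 members up (9 and 3 adjusted over the list alone). The adjusted p values with an estimated correlation were 0.0889 and 0.0524. No list call between the vehicle times was lost in more than 3 of the 16 other settings.

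The effect of 10 µg/ml differed between 48 h and 24 h for 1459 genes with EBC-46 and 1741 with EBC-211, by a test of the difference of effects. KRT15 was lower than vehicle at 24 h and higher at 48 h, a difference of 4.39 ± 0.36 with EBC-46 and 4.35 ± 0.36 with EBC-211. KRT13 differed by 2.83 ± 0.37 and 2.63 ± 0.37 in the same order. HSPH1 differed by -1.12 ± 0.16 and -1.26 ± 0.16, more negative at 48 h. Heat shock genes as a list were called more negative at 48 h, with 6 and 6 of 16 members called (6 and 8 adjusted over the list alone), and this was the only list call of 11 for EBC-46 and 9 for EBC-211 that held with an estimated correlation. Mitosis and G2/M, more positive at 48 h, had 28 and 22 of 39 members called (34 and 30 adjusted over the list alone). Its adjusted p values with an estimated correlation were 0.066 and 0.129. Of the differing genes 860 and 1019 were more positive at 48 h. With the BeadChip as a block the counts were 2776 and 3232, and without replicate 3 of every group they were 590 and 850, without replicate 4 899 and 830. For EBC-46 the count without replicate 2 was 794. With median centring in place of quantile normalization the counts were 792 and 959.

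**Figure D3:**
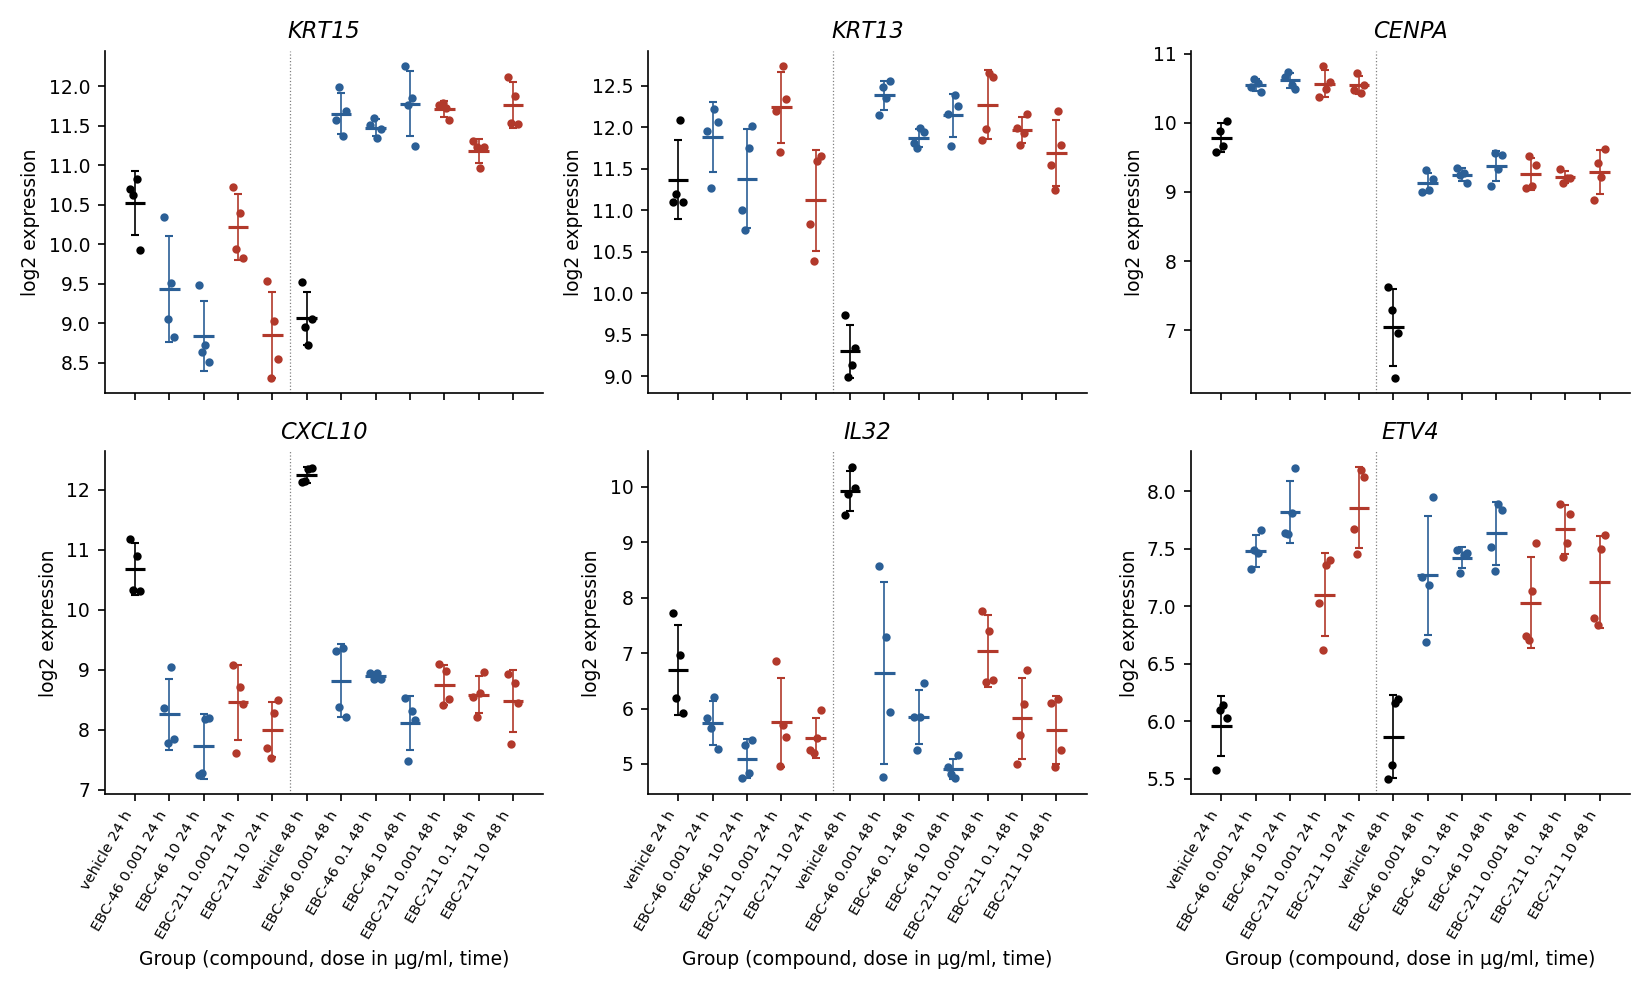
Normalised log2 expression of 6 genes on each of the 48 arrays, by group. Points are arrays, with 4 per group, horizontal lines are group means and error bars are SD. Groups are ordered by time, compound and dose in µg/ml, and axes do not start at 0. KRT15, KRT13 and CENPA are lower in vehicle at 48 h than in vehicle at 24 h, and at 48 h the treated groups lie above vehicle for these genes and below it for CXCL10 and IL32.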

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

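The tests of explanations in this part, and their predictions, were chosen after the results they bear on were seen.

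Every treated group, even at 0.001 µg/ml, differed from vehicle of its time in far more genes than the doses differed from each other. A gradual trend along the sections of a BeadChip was tested with treated groups at 48 h that lie 8 sections apart, EBC-46 at 0.001 and EBC-211 at 10 µg/ml. They differed in 239 genes against 3224 for EBC-46 at 0.001 µg/ml and vehicle only 2 sections apart, so such a trend is excluded as the main source. A response near its full size at the lowest dose is not excluded. Over genes that changed with the other compound at 10 µg/ml on 2 BeadChips, the change at 0.001 on the other 2 averaged between 0.799 and 0.887 of that at 10 µg/ml in the 4 pairings of compound and time, the lowest of 6 splits being 0.749, which measures the pattern and does not explain it. Vehicle arrays handled or placed apart from all treated arrays could produce the same ratios. Vehicle occupied the same 2 sections on every BeadChip, so these data cannot tell it from a response to the compounds, and each comparison with vehicle carries this limit.

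The changes against vehicle at 48 h ran opposite to the change of vehicle between 24 h and 48 h, with mitosis genes higher and wound-activated keratinocyte genes lower. Of the 19 lists called between the vehicle times, 15 were called the opposite way in at least 1 of the 6 treated groups at 48 h, 11 of them in all 6, and 3 were called in none. Cholesterol synthesis ran the same way, called up in vehicle over time and up against vehicle in 5 of the 6. Both sides of these list calls rest on the same vehicle arrays at 48 h, as do the 6 groups. Noise in those arrays favours opposite calls, and the lists were not tested with separate vehicle arrays. Across genes the correlation was -0.737 to -0.645, where shared vehicle arrays alone give -0.50. With separate vehicle arrays on the 2 sides, over 6 splits and 6 groups, the weakest correlation was -0.433, so noise of shared arrays alone is excluded as the source. An offset common to all vehicle arrays at 48 h would enter both sides of every split, so the splits cannot exclude it. Whether treated cultures moved less along the time course of vehicle stays open. Of the 1661 genes that changed in vehicle, 1288 to 1424 moved the same way between the times with either compound at 0.001 or 10 µg/ml. Over these 1661 genes the highest slope of the treated on the vehicle time change was 0.672. An opposite change at 48 h and the choice of genes by the vehicle change push this slope below 1, so it decides nothing.

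Replicate 2 of EBC-46 at 0.001 µg/ml and 48 h stood apart from its group, with a ratio of gap to range of 0.981 for its mean correlation. 846 features lay over 1 log2 unit from the value that group and BeadChip give, and of 12 wound-activated keratinocyte genes 11 lay below, with a median of -1.31. Its mean signal was the lowest of the 48 arrays, and its array weight was 0.177. The other 6 arrays among the 6 dimmest by mean or by median signal had weights of 0.707 to 1.5. Of these, 3 had a lower median signal than this one, so a low signal as such did not go with a low weight. Each had a higher mean signal than this array, so dim hybridisation is not excluded for it. A swap with vehicle or the other time is excluded, since it correlated at 0.971 to 0.973 with the 6 treated groups at 48 h, highest with EBC-211 at 0.1 µg/ml, against 0.964 with vehicle at 24 h, 0.954 with vehicle at 48 h and 0.953 to 0.961 with treated groups at 24 h. What set this culture or sample apart was not found. Replicate 4 of EBC-211 at 10 µg/ml and 48 h, left out in added fits of the counts that rest on it, had a score of 6.52 on principal component 2. The other arrays of BeadChips 3 and 4 had -28.8 to -8.93, and those of BeadChips 1 and 2 had 3.40 to 33.3. Its array weight was 1.15, and no explanation was tested.

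The effect of 10 µg/ml differed between 48 h and 24 h for 1459 genes with EBC-46 and 1741 with EBC-211, and 124 and 166 genes had changed in opposite directions, KRT15 among them. Of 48 groups of array measures 4 held a single array apart by Dixon's ratio, which picks out about 1 in 20 by chance. Besides the array above these were the mean signal of replicate 3 of vehicle at 48 h (0.886), the share of probes detected in replicate 3 of EBC-211 at 10 µg/ml and 48 h (0.950), and the mean correlation of replicate 2 of EBC-46 at 0.001 µg/ml and 24 h (0.889). Of 243 sets of 4 values of named genes, 12 held a value apart by the same ratio, near the share that chance gives. They were MANCR (0.900) and CCL2 (0.871) in EBC-46 at 10 µg/ml and 24 h, RSAD2 (0.832) in EBC-46 at 0.001 µg/ml and 24 h, RELB (0.992) and KRT13 (0.896) in vehicle at 24 h, CDKN1A (0.894) and MMP10 (0.917) in EBC-211 at 10 µg/ml and 24 h, S100A7 (0.865) and SERPINB3 (0.932) in vehicle at 48 h, SOD2 (0.877), ITGA5 (0.916) and TAGLN (0.880) in EBC-46 at 10 µg/ml and 48 h. Among the 92 probes without a detection p, 19 were brighter than every undetected probe on all 48 arrays, and with all 92 tested 5 and 6 of them changed with EBC-46 and EBC-211 at 10 µg/ml and 48 h.

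Predictions for the splits of arrays, except the groupings within replicate numbers, were written before the splits were run. For comparisons with vehicle the real grouping gave more genes than all other splits, that is 1 of 35 gave as many. By the share under 0.05 written beforehand chance is excluded. Most of these splits, though, put both arrays of some BeadChip on one side. At 24 h the real count and the highest other were 2998 against 824, 3174 against 760, 2410 against 608 and 3521 against 979, for EBC-46 at 0.001 and 10 µg/ml and EBC-211 likewise. At 48 h they were 3224 against 893, 3183 against 283, 3480 against 523, 2652 against 325, 3282 against 420 and 3356 against 999, for EBC-46 and then EBC-211 in rising dose. By the same share chance is excluded for vehicle between times (1661 against 357). For 10 against 0.1 µg/ml 1 of 35 splits gave as many with EBC-46 (8 against 0) and with EBC-211 (4 against 1). Both of these counts fell with any replicate number left out, so chance is not excluded for them. For the differences of effects, 4 and 3 of 100 random groupings gave as many genes (1459 against 2776 and 1741 against 2139 the highest other). Of 100 groupings that keep 1 array of each group in every replicate number 4 and 8 did (highest other 2985 and 2880). Both kinds mix vehicle with compound and 24 h with 48 h, so their counts carry those effects and do not decide. With the additive effects of compound, time and BeadChip taken out first, 1 and 1 of 100 groupings within replicate numbers gave as many (1459 against 508 and 1741 against 490). By this test alone, added after the data were seen, chance is excluded for both compounds. The 8 splits that part every replicate number, too few for a share under 0.05 on their own, gave at most 8 genes at 24 h and 647 at 48 h against vehicle, 357 for vehicle between times and 0 for 10 against 0.1 µg/ml, the real grouping apart. For EBC-46 against EBC-211 at 10 µg/ml and 24 h 2 of 35 splits gave as many (4 against 24). The 24 came from setting BeadChips 1 and 2 against 3 and 4, which points to a structure of the BeadChips, and the other splits that part every replicate number gave at most 1. In the other 4 comparisons of the compounds, with no gene, all 35 gave as many, the highest other counts being 28, 718, 0 and 1, of which 718, at 0.001 µg/ml and 48 h, came from the same split of BeadChips.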

How the results depend on the processing

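The fits on replicates 1 and 2 or 3 and 4 and without single arrays were chosen after the data were seen. Among the named genes, the correlations of the compounds and the lists called against vehicle or between the vehicle times, none reversed its direction under any alternative. List calls in other comparisons were not refitted, apart from the estimated correlation. List calls kept their direction and side of the threshold in 2733 tests and lost it in 179, of which 67 came with an estimated correlation. Named genes kept theirs in 2183 tests and lost the call in 181, most of them in comparisons of doses or of the compounds, and none with the block. With the BeadChip as a replicate block the counts rose to 4500, 3919 and 4124 for 0.001 µg/ml of EBC-46 and EBC-211 at 24 h and EBC-211 at 48 h, 2663 for vehicle over time, 34 and 70 for 10 against 0.1 µg/ml, 2776 and 3232 for the differences of effects, and 1, 7, 4, 4 and 1 for the compounds against each other. The other counts against vehicle rose too, to 4665 and 5056 for 10 µg/ml of EBC-46 and EBC-211 at 24 h. At 48 h they were 4807, 4627 and 4972 for EBC-46 in rising dose. For EBC-211 at 0.1 and 10 µg/ml and 48 h they were 4772 and 4987. With the block 2 list calls were lost. For the small counts, EBC-46 against EBC-211 at 10 µg/ml and 24 h, EBC-46 at 10 against 0.1 µg/ml, and EBC-211 likewise, the values were 2, 11 and 6 without background correction, 3, 3 and 0 with median centring, 4, 10 and 7 with the deposited values, 4, 4 and 2 with no filter, 1, 4 and 7 with detection on all 48 arrays, 3, 20 and 19 with array weights and 0, 17 and 1 with the compared groups alone. Where no gene differed between the compounds, 10 µg/ml at 48 h gave 1 without background correction and 1 with the deposited values, 0.1 µg/ml gave 1 with no filter and 5 with array weights, and 0.001 µg/ml at 24 h gave 3 with array weights. Median centring gave 792 and 959 for the differences of effects and shifted the median of all genes by up to 0.122, for EBC-46 at 0.1 µg/ml and 48 h. The compared groups alone gave 1433 for EBC-46 at 0.001 µg/ml and 48 h. The cause was not tested for these. Replicates 1 and 2 alone, with fewer arrays, gave 1507, 1924, 1106 and 1675 at 24 h against vehicle, 1807, 2049, 1339, 2009 and 1877 at 48 h from EBC-46 at 0.1 µg/ml upward and EBC-211 in rising dose, 637 for vehicle over time, 302 and 389 for the differences of effects, 1 and 0 for 10 against 0.1 µg/ml, 0 for the compounds at 10 µg/ml and 24 h and 364 at 0.001 µg/ml and 48 h, the group with the array apart. Replicates 3 and 4 alone gave 9 for the compounds at 10 µg/ml and 24 h, 1 at 0.1 µg/ml and 1 and 0 for 10 against 0.1 µg/ml. With 1 replicate number or 1 array left out, and so fewer arrays, counts ranged over 1969 to 2462 and 1456 to 1828 for 0.001 µg/ml of EBC-46 and EBC-211 at 24 h, 2268 to 3003 for EBC-211 at 10 µg/ml, 1730 to 2186 and 2232 to 2848 for EBC-211 at 0.001 and 10 µg/ml at 48 h, 1043 to 1470 for vehicle over time, 590 to 1155 and 830 to 1595 for the differences of effects, 1 to 4 and 0 to 2 for 10 against 0.1 µg/ml, and 1 to 3 and 0 to 2 for the compounds at 10 µg/ml and 24 h or 48 h. The correlation of the compounds is given for 0.001 and 10 µg/ml at 24 h, then 0.001, 0.1 and 10 µg/ml at 48 h. It was 0.714, 0.7588, 0.7177, 0.7885 and 0.7959 with vehicle arrays split, and so fewer for each compound and on different BeadChips. With the deposited values it was 0.9516, 0.9454, 0.9049, 0.9655 and 0.9595, and with 1 replicate number left out 0.902 to 0.9162, 0.8953 to 0.9203, 0.8289 to 0.9022, 0.9291 to 0.9399 and 0.9166 to 0.9342. The low signal limits dim genes, as 27.1% to 33.4% of probes were detected.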

Other observations

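The comparisons in this part, and the genes named for them, were chosen after the data were seen.

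As a list, ERK pathway feedback genes were called higher at 10 than at 0.001 µg/ml. ETV5, an ETS transcription factor gene of that pathway, was higher at 10 µg/ml by 0.91 ± 0.13 with EBC-46 and 1.11 ± 0.13 with EBC-211 at 24 h (log2, SE, n = 4), and SPRY1, a gene of the Sprouty inhibitors, by 0.98 ± 0.13 with EBC-211 at 48 h. The call held in all 4 pairings of compound and time, with 1, 2, 3 and 3 of 17 members up in the order EBC-46 and EBC-211 at 24 h and then at 48 h (3, 5, 5 and 5 adjusted over the list alone), and held with an estimated correlation in each. It was not called between 0.1 and 10 µg/ml at 48 h (adjusted p = 0.572 and 0.818, camera), nor against vehicle at 10 µg/ml and 48 h (0.0879 and 0.148). At 24 h TAGLN was lower at 10 µg/ml with EBC-46 (-1.74 ± 0.31) and EBC-211 (-1.85 ± 0.31). With EBC-46 the other 3 genes that differed were the chemokine gene CCL2 (-1.48 ± 0.28), the collagenase gene MMP13 (-1.23 ± 0.24) and KLF9, detected on 1 of 4 arrays at 10 µg/ml (at least 1.93-fold lower). With EBC-211 S100A8 (-2.84 ± 0.67) and MMP10 (-2.36 ± 0.27) were lower. At 48 h S100A7A changed by -2.57 ± 0.60 with EBC-46, and SAA4 was detected on 1 of 4 arrays at 10 µg/ml and at least 2.38-fold lower. With EBC-211 S100A12, an alarmin gene, and KRT1, a keratin gene of terminal differentiation, were undetected at 10 µg/ml and at least 2.39-fold lower and at least 2.15-fold lower. In limma 5, 158, 119 and 54 features differed, and 71, 581, 520 and 248 with the BeadChip as a block. Leaving out 1 replicate number moved these counts to between 0 and 8, 40 and 133, 8 and 73, and 8 and 25, the lowest without replicate 3 in each. On the arrays of the compared groups alone they were 0, 34, 0 and 14, and with median centring 3, 70, 26 and 14. Without replicate 4 of EBC-211 at 10 µg/ml and 48 h alone, the last count was 22. For EBC-211 1 of 35 splits gave as many at 24 h (158 against 2 in the highest other split) and at 48 h (54 against 0). Most of these splits put both arrays of some BeadChip on one side. For EBC-46 2 of 35 splits gave as many, the real one and BeadChips 1 and 2 against 3 and 4 (5 against 28 at 24 h and 119 against 997 at 48 h), which points to a structure of the BeadChips. Among the 8 splits that part every replicate number as the real one does, too few for a share under 0.05, the highest other counts were 0 and 1.

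Treated cultures changed between 24 h and 48 h as well. KRT15 rose by 2.22 ± 0.25, 2.94 ± 0.25, 1.49 ± 0.25 and 2.91 ± 0.25 with EBC-46 at 0.001 and 10 µg/ml and EBC-211 at 0.001 and 10 µg/ml, where in vehicle it changed by -1.45 ± 0.25. SERPINB4 changed by 3.19 ± 0.52, 1.78 ± 0.52, 2.60 ± 0.52 and 2.32 ± 0.52. In the same order 10, 8, 10 and 9 of 12 wound-activated keratinocyte genes rose (11, 8, 10 and 9 adjusted over the list alone), and 37, 36, 37 and 37 of 39 mitosis genes fell (37, 37, 38 and 38 adjusted over the list alone). In all 3683, 3462, 2730 and 4110 genes changed, and 5218, 5017, 4268 and 5627 with the BeadChip as a block. In each, 1 of 35 splits gave as many (3683 against 1321, 3462 against 1204, 2730 against 397 and 4110 against 1125 in the highest other split). Most of these splits put both arrays of some BeadChip on one side.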
